A study of Rattus norvegicus with 24 samples.

How the data were processed

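RNA sequencing was carried out on the left ventricle, the adrenal gland and the superior cervical ganglion of 24-week-old rats of 2 inbred strains, the spontaneously hypertensive rat (SHR) and the Wistar-Kyoto rat (WKY), with 4 libraries for each of the 6 groups and 24 libraries in all. Per the labels' protocols, RNA was extracted with Trizol, total RNA entered a KAPA RNA HyperPrep library and the libraries were read on a BGISEQ-500 instrument. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the build Rnor_6.0, without a role or an order. The annotation, the filters and the number of reads are not given in the sources used here. Each sample was placed in its group by its title, and the replicate number is the one in the title.

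The deposited table holds 22864 genes with an NCBI gene identifier and a symbol. The values are FPKM, fragments normalized to transcript length and library size, with 1 column per library, per the file headers. They are written with 2 decimals. The same table holds log2 ratios of SHR over WKY for each tissue and their q-values, both computed by the authors, per the file headers; they are quoted only as counts and only under the name of the authors' deposited table. In 2358 genes every library was blank, which left 20506 genes. Another 27 symbols had been turned into dates and were restored from the reference gene table of assembly GRCr8 by gene identifier, which held 20690 of the identifiers of the deposited table. That assembly is not the one of the deposited values, so it was used for names and for the order of neighbouring genes, and no coordinates are given. Cyp11b1 and Hsd3b1 are not analysed here.

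Sequencing depth could not be recovered. FPKM carries no read count, and low values did not fall on common steps that would give relative depth. The sum of FPKM was 533805 to 549167 in the left ventricle, 493051 to 517693 in the adrenal gland and 455530 to 465993 in the ganglion, and the number of genes at an FPKM of at least 1 was 12247 to 12470, 12104 to 12728 and 12737 to 12999. No interval that needs a read count is given. The precision of each value rests on the spread of 4 libraries.

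Values were tested on a log scale, log2(FPKM + 1), with limma 3.58.1 in R 4.3.3, using a trend in the prior variance and robust empirical Bayes moderation, among genes with an FPKM of at least 1 in at least 4 of the 8 libraries of a tissue. The p-values are 2-sided and Benjamini-Hochberg adjusted within a tissue, with a threshold of 0.05. Fold changes are SHR minus WKY on this scale, which understates the change of weakly expressed genes, and their error is the standard error (SE) of limma. Values of FPKM are means ± SD of 4 libraries. Whether a strain difference itself differed between tissues was tested by interaction contrasts in a joint model of all 24 libraries, on genes with an FPKM of at least 1 in at least 4 libraries. Genes called in the same direction in all 3 separate fits were counted beside the count that independent lists would give.

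A total of 30 gene lists for pathways, cell types and earlier SHR genetics was fixed before the data were examined, as were the tests, the rule for named genes and the main alternatives. Lists with at least 5 measured members were tested with camera (limma) at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a tissue, and again with an estimated correlation. The median, the mean and the direction of the set test differed in sign in 5 of 15 lists in the left ventricle, 3 of 20 in the adrenal gland and 5 of 17 in the ganglion, none of them called. The list from earlier SHR genetics has no common direction and was only counted. Called members are also counted with p adjusted over the list alone. The named genes are fixed genes of each tissue, the 5 higher and 5 lower genes with the largest fold change among those past the threshold with a mean FPKM of at least 5 and no overlap between strains, up to 3 members past the threshold of each called list by smallest adjusted p and up to 1 of every other list, the 4 genes with the largest difference for each pair of tissues, and the 4 higher and 4 lower genes with the largest change common to the 3 tissues. Any member of the genetics list past the threshold could be named. Other list members appear where a count of 5 or fewer is broken down, and those were chosen after their values were seen. A few genes that these rules would name are included in the counts and tests but are not reported here. Genes with near-identical copies are marked as uncertain, because reads can be split between copies: this concerns Ndufa10l1 and Ndufa10, the Cyp11b and Hsd3b genes, the RT1 genes, the globin genes, Oas1g, Tuba1c and Hist1h2bk.

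The test was tried on simulated data with known changes drawn on the real genes. Noise was drawn independently for each gene, and far fewer genes were changed than the strains called. The rates hold for that setting and need not hold for genes that vary together. With 100 genes changed by each size in 12451 genes of the left ventricle, it recovered 52% of changes of 0.5 and 93% of changes of 1 on the log2 scale, with 2 false calls; in the adrenal gland (12589 genes) it recovered 66% and 91%, with 15 false calls, and in the ganglion (12987 genes) 73% and 95%, with 11. In the contrast of the adrenal gland and the left ventricle, run on 14682 genes, it recovered 48% and 89%, with 7 false calls.

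The alternatives were a pseudocount of 0.1, no filter, a stricter filter (FPKM of at least 5), median-of-ratios scaling, quantile normalization, the replicate number as a block, array weights, a joint fit, a minimum of 2-fold, another form of the set test, and leaving out each library in turn. Figures were drawn with matplotlib.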

Results

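Gene expression was measured in 3 tissues of the sympathetic and cardiac system of SHR, a rat strain with inherited hypertension and enlargement of the left ventricle, and of the related WKY strain, at 24 weeks of age. The question in each tissue was which transcripts differ between the hypertensive strain and its control. Each tissue gave 4 libraries of SHR and 4 of WKY. Levels are given as mean ± SD of FPKM (n = 4), and differences as SHR minus WKY on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. The sequencing depth is unknown. The labels do not say that the libraries came from separate rats, so p-values measure the spread between these libraries, which may be technical. Correlations of log2(FPKM + 1) between libraries of the same strain were 0.983 to 0.991 in the left ventricle, 0.979 to 0.991 in the adrenal gland and 0.988 to 0.994 in the superior cervical ganglion. Between strains they were 0.966 to 0.975, 0.937 to 0.955 and 0.976 to 0.985. The highest share of genes with equal values, to 2 decimals, in a pair of libraries was 0.53%, 0.53% and 0.65%, so no library repeated another. The first principal component separated the strains in every tissue and held 51.3%, 67.4% and 44.1% of the variance.

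In the left ventricle, 8 of 14 measured genes of the hypertrophic and fetal programme were higher in SHR and none lower. The camera adjusted p was 3.72e-05 (adjusted p = 0.269 with an estimated correlation). Acta1, skeletal actin of the fetal heart, reached 2492 ± 466 FPKM against 1051 ± 351 in WKY, a log2 difference of 1.29 (SE 0.25, adjusted p = 0.0103). Nppb, which encodes brain natriuretic peptide, was at 623 ± 187 against 345 ± 33.2, a difference of 0.81 (SE 0.20, adjusted p = 0.0226). The stress-responsive sarcomere and Z-disc genes Ankrd1, Csrp3 and Fhl1 rose by 0.79, 1.20 and 1.67. Nppa, atrial natriuretic peptide, was at 3178 ± 1306 and 1309 ± 815 and did not pass (difference 1.43, adjusted p = 0.118). The myosin heavy chains Myh6 and Myh7 (differences -0.22 and -0.24, adjusted p = 0.0702 and 0.0575) and the calcium pump gene Atp2a2 (-0.09, adjusted p = 0.456) did not pass either. Nppb was no longer past the threshold without SHR replicate 2 or without WKY replicate 1, 3 or 4 (adjusted p = 0.0550 to 0.0627), while Myh6 passed without WKY replicate 1 (adjusted p = 0.0250) and Myh7 without WKY replicate 2 (adjusted p = 0.0363).

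**Figure D1:**
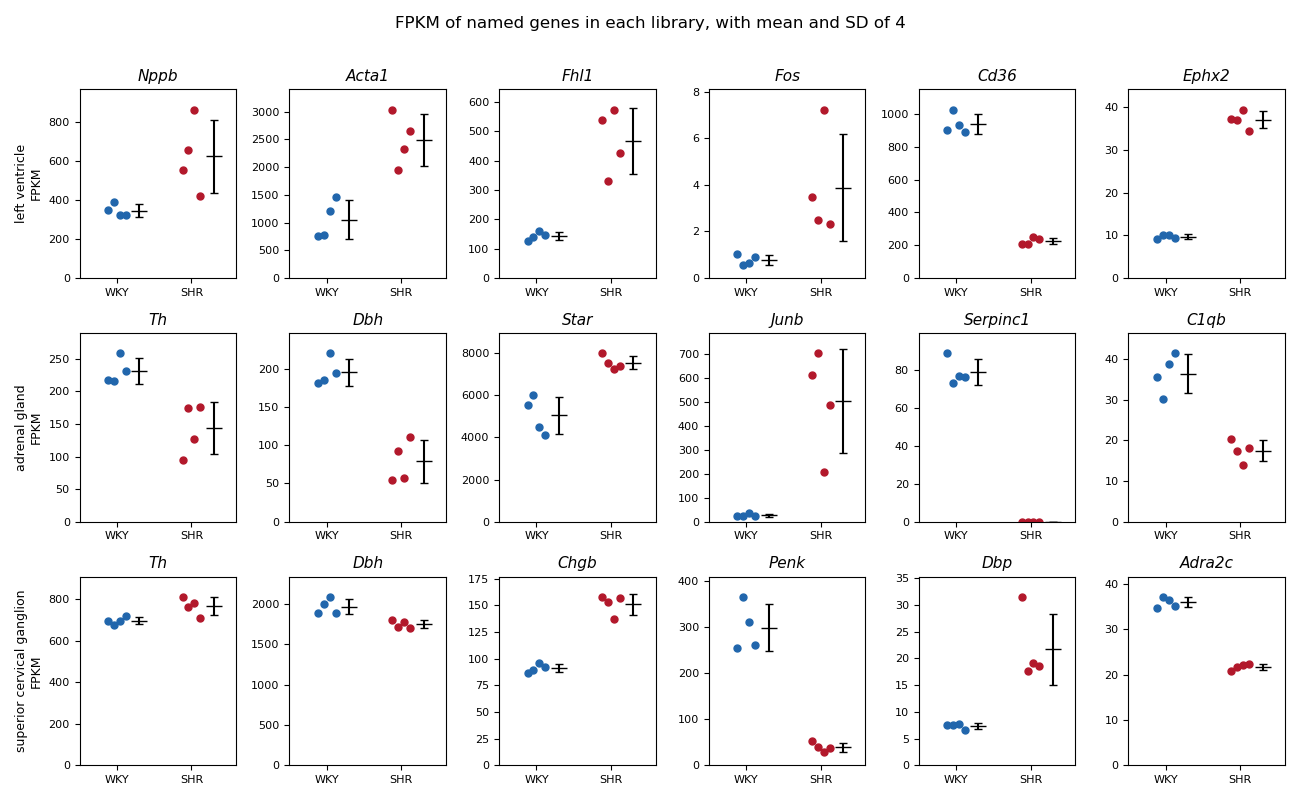
FPKM (linear axes from 0) of 6 named genes in each tissue, with a point for each of the 4 WKY (blue) and 4 SHR (red) libraries and a black bar for the mean and SD. In the left ventricle Cd36 averages 225 in SHR against 938 in WKY, in the adrenal gland Junb averages 503 against 26.2, and in the ganglion Penk averages 39.5 against 298.

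The hypertrophy and fetal gene list had a median difference of 0.87 (8 higher and 1 lower adjusted over the list alone). Of 21 immediate early genes, which respond within minutes to stimulation, 10 rose and none fell (14 and 1 adjusted over the list alone). The camera adjusted p was 4.17e-08 (adjusted p = 0.269 with an estimated correlation). Among them were Fos with 3.88 ± 2.30 against 0.78 ± 0.21 FPKM, Myc (1.18) and Btg2 (0.64). Handling or the order of collection cannot be told apart from strain for these genes, because the labels give neither time nor order. Antioxidant genes rose in 8 of 21 cases and fell in 1, Gsta4 (9 and 1 adjusted over the list alone). This list had a camera adjusted p of 2.41e-04 (adjusted p = 0.135 with an estimated correlation) and was led by the epoxide hydrolase gene Ephx2 (1.83, SE 0.06), Srxn1 (1.07) and Txnrd1 (0.45). Leukocyte markers rose in 6 of 16 cases with none lower (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.00178 (adjusted p = 0.727 with an estimated correlation). They included the complement genes C1qa, C1qb and C1qc with differences of 0.83, 0.99 and 0.96. In SHR replicate 3 the mean of the leukocyte list was 3.89 as log2(FPKM + 1), within the WKY range of 3.58 to 4.07. The other SHR libraries were at 4.32 to 4.53.

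Interferon-response genes were the group with the most members lower in the SHR ventricle. Of 24 members, 18 were lower, for example Ddx58, an RNA sensor (-1.08), and Stat2 (-0.77), and 1 was higher (20 and 1 adjusted over the list alone). The camera adjusted p was 4.17e-08 (adjusted p = 0.673 with an estimated correlation). The exception was Ifit1, at 14.3 ± 12.2 against 0.05 ± 0.04 FPKM. SHR replicate 2 stood apart here: its mean of the list was 4.70 as log2(FPKM + 1), the other SHR libraries were at 3.44 to 3.71 and the WKY libraries at 4.61 to 4.94. Fatty acid oxidation genes fell in 8 of 24 cases and rose in none (10 and 0 adjusted over the list alone), with a camera adjusted p of 0.0109 (adjusted p = 0.673 with an estimated correlation). They included the fatty acid transporter Cd36, at 225 ± 20.6 against 938 ± 61.4 FPKM (-2.06, SE 0.07, adjusted p = 7.44e-08), Ech1 (-0.49) and the fatty acid binding protein gene Fabp3 (-0.41). Without WKY replicate 4 this list had a camera adjusted p of 0.0841. Oxidative phosphorylation genes fell in 6 of 31 cases, including Ndufb8 (-0.29), Ndufs3 (-0.23) and Ndufa10 (-0.40), whose level is uncertain because of a near-identical copy, and rose in 1 (7 lower and 1 higher adjusted over the list alone). Their camera adjusted p was 0.0242 (adjusted p = 0.727 with an estimated correlation). This list no longer passed with median-of-ratios scaling (camera adjusted p = 0.136) or without SHR replicate 4 or WKY replicate 2 or 4 (camera adjusted p = 0.0711 to 0.0940).

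Other lists of the left ventricle did not pass the set test. Matrix and fibrosis genes went both ways, 9 of 30 higher and 3 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.132), and passed in the higher direction without SHR replicate 1 or 3 or WKY replicate 3 (camera adjusted p = 0.0323 to 0.0478; adjusted p = 0.795 with an estimated correlation in all 8 libraries). Tgfb2 rose by 1.61 and Spp1, which encodes the matrix protein osteopontin, by 3.77, while Col6a1, Eln and Ogn fell. Contractile and calcium handling genes were higher in 6 and lower in 4 of 18 cases (6 and 5 adjusted over the list alone), the 4 being Tnnt2 (-0.34), Tnni3, Kcnd2 and Kcnd3. Glycolysis genes were higher in 4 and lower in 6 of 20 (4 and 6 adjusted over the list alone), with Eno1 up by 1.54. Adrenergic, angiotensin, endothelin and natriuretic signalling genes were higher in 4 and lower in 4 of 20 (4 and 4 adjusted over the list alone), among them the endothelin receptor gene Ednra (-0.69). Clock genes were higher in 3 and lower in 2 of 17 (3 and 3 adjusted over the list alone), the 2 being Npas2 (-0.83) and Nr1d1. Among the cell type lists, endothelial markers were lower in 2 of 12 (4 adjusted over the list alone), Egfl7 and Tie1. Smooth muscle and pericyte markers were higher in 2 of 11, Mustn1 and Des (1 adjusted over the list alone), and Mustn1 (0.79) lost its call without SHR replicate 1 or WKY replicate 3 or 4 (adjusted p = 0.0517 to 0.0613). Atrial markers were higher in 2, Tbx5 and Pam, and lower in 1, Dkk3, of 7 (2 and 2 adjusted over the list alone). With fewer than 5 measured members and no set test, adipocyte markers had 1 higher (Cfd) and 1 lower (Cidea) of 4, with 1 and 1 also when adjusted over the list alone. Erythroid markers had Alas2 and the globin gene Hbb lower of 4, and all 4 lower when adjusted over the list alone. Hbb, at 509 ± 58.4 against 1088 ± 410 FPKM, lost its call in 6 of the refits with a library left out, those without SHR replicate 1, 2, 3 or 4 and without WKY replicate 1 or 2 (adjusted p = 0.0588 to 0.0815). None of 4 cell cycle genes passed (2 lower adjusted over the list alone).

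In all, limma called 2644 of 12451 genes in the left ventricle, 1146 higher and 1498 lower in SHR, of which 252 changed at least 2-fold. Higher calls made up 43.3%, or 52.1% with median-of-ratios scaling and 49.3% with quantile normalization. The largest higher genes were Ndufa10l1 (84.5 ± 3.90 against 0.81 ± 0.40 FPKM), Spp1 (29.9 ± 15.6 against 1.24 ± 1.14), Ifit1, Reg3b and Thbs4, a matrix glycoprotein gene (2.63). The largest lower genes were Hba-a1 (0.19 ± 0.24 against 16.3 ± 6.48), the class I histocompatibility gene RT1-N2 (4.13 ± 0.68 against 28.8 ± 5.93), Ccdc78, Serhl2 (11.9 ± 1.35 against 65.9 ± 2.97) and Oas1g. Reads of Ndufa10l1, Hba-a1, RT1-N2 and Oas1g can be shared with near-identical copies, so their levels are uncertain. Oas1g lost its call without SHR replicate 1 or 4 or WKY replicate 3 (adjusted p = 0.0506 to 0.0537). Of 14 genes named in earlier SHR genetics, 2 were higher, Ephx2 and Gstm1 (0.39), and 4 lower, Cd36, Endog, a mitochondrial nuclease gene linked to cardiac mass (12.5 ± 1.70 against 53.6 ± 3.23 FPKM), Ogn (-0.65) and Stim1 (-0.31), with the same counts adjusted over the list alone. On the second principal component SHR replicate 3 stood at -20.1, with the other SHR libraries at -1.57 to 14.2.

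In the adrenal gland, which holds a steroid-making cortex and a catecholamine-making medulla, 12 of 15 catecholamine genes were lower in SHR and 16 of 18 immediate early genes higher (adjusted p = 0.589 for either list with an estimated correlation). Th, the rate-limiting enzyme of catecholamine synthesis, was at 143 ± 39.7 FPKM in SHR and 231 ± 19.6 in WKY (-0.73, SE 0.19, adjusted p = 0.0154). Dbh, which makes noradrenaline, was at 78.6 ± 28.1 against 195 ± 17.6 (-1.36, SE 0.23, adjusted p = 0.00223), and Pnmt, which makes adrenaline, at 201 ± 80.8 against 368 ± 32.7 (-0.96, SE 0.27, adjusted p = 0.0231). Star, which delivers cholesterol for steroid synthesis, was higher in SHR, at 7547 ± 319 against 5043 ± 898 (0.60, SE 0.11, adjusted p = 0.00279). The aldosterone synthase gene Cyp11b2 was at 3111 ± 210 against 2490 ± 80.4 (0.32, SE 0.06, adjusted p = 0.00200), a value that is uncertain because its sequence is close to that of other Cyp11b genes. Pnmt lost its call without WKY replicate 2, 3 or 4 (adjusted p = 0.0544 to 0.0586).

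The catecholamine list had 12 of 15 members lower and 1 higher, Spr (13 and 1 adjusted over the list alone). Ddc differed by -1.27, and the list had a camera adjusted p of 8.08e-04 (adjusted p = 0.589 with an estimated correlation). Secretory granule and neuropeptide genes were lower in 12 of 17 cases and higher in none (13 and 0 adjusted over the list alone), with a camera adjusted p of 8.08e-04 (adjusted p = 0.593 with an estimated correlation). They included Penk, the enkephalin precursor (2.16 ± 0.51 against 16.1 ± 3.52 FPKM), Syt4 and Cadps. Of 18 neuronal identity genes, 12 were lower, for example Gap43 (-1.50) and Gata2 (-1.17), and 2 higher, Tubb3 (0.80) and Nefh (12 and 3 adjusted over the list alone). The camera adjusted p was 0.00816 (adjusted p = 0.593 with an estimated correlation). Leukocyte markers were lower in 14 of 15 cases (14 adjusted over the list alone), for example Cd74 (-1.27), C1qa (-1.09) and C1qb (-1.03), with a camera adjusted p of 1.14e-05 (adjusted p = 0.589 with an estimated correlation). Endothelial markers were lower in 11 of 12 (11 adjusted over the list alone), for example Tek (-1.02), Cldn5 (-0.92) and Pecam1 (-0.57), with a camera adjusted p of 8.08e-04 (adjusted p = 0.589 with an estimated correlation). All 4 measured erythroid markers were lower (4 adjusted over the list alone), by a median of -1.83; Alas2 was at 0.39 ± 0.18 against 1.88 ± 0.10 FPKM.

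Among 18 immediate early genes, 16 rose and none fell, with a median difference of 1.76 (16 and 0 adjusted over the list alone). The list's camera adjusted p was 1.05e-09 (adjusted p = 0.589 with an estimated correlation). Junb was at 503 ± 216 FPKM against 26.2 ± 5.60 (4.09, SE 0.37, adjusted p = 1.72e-04), Ier2 at 71.8 ± 17.0 against 19.8 ± 0.96 and Ier3 at 101 ± 25.1 against 26.3 ± 2.80. SHR replicate 3 stood apart from the other SHR libraries on the second principal component, at -25.7 against 6.15 to 13.2, and its mean of the immediate early genes was 4.61 against 5.62 to 6.02 in the other SHR libraries and 3.44 to 3.57 in WKY, as log2(FPKM + 1). Without SHR replicate 3 the list had 17 members higher.

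Oxidative phosphorylation genes were lower in 25 of 31 cases and higher in none, for example Ndufb8 (-0.64) and Ndufa10 (-0.62) (26 and 0 adjusted over the list alone). They had a camera adjusted p of 5.96e-07 (adjusted p = 0.589 with an estimated correlation). Matrix genes were lower in 17 of 30 cases, among them the fibrillar collagen genes Col5a1 (-1.22) and Col5a2 (-0.98), and higher in 2, Timp1 and Spp1 (18 and 2 adjusted over the list alone). Spp1 was at 2981 ± 178 against 693 ± 115 FPKM, and the list had a camera adjusted p of 0.00482 (adjusted p = 0.635 with an estimated correlation). Interferon-response genes were lower in 14 of 24, for example Mx1 (-2.16), and higher in 2, among them Ifit1 (3.52), or 15 and 2 adjusted over the list alone. The camera adjusted p was 0.00945 (adjusted p = 0.722 with an estimated correlation). As in the left ventricle, SHR replicate 2 stood apart, with a mean of the interferon list of 4.89 against 3.54 to 3.68 in the other SHR libraries and 4.58 to 4.97 in WKY. Leukocyte and endothelial markers, with medians of -0.84 and -0.57, were lower in the same strain as these 3 lists.

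Steroidogenesis genes did not pass the set test, with 6 of 20 higher and 3 lower, Agtr1a, the angiotensin receptor gene (-1.13), Fdx1 and Nr0b1 (6 and 3 adjusted over the list alone; camera adjusted p = 0.579). Cholesterol synthesis and uptake genes were higher in 4 of 23, among them Stard4 (72.3 ± 8.52 against 10.3 ± 3.22 FPKM), Pmvk and Dhcr7, and lower in 4, Mvd, Sqle, Lss and Tm7sf2 (4 and 2 adjusted over the list alone). Ion channel and nicotinic receptor genes had 3 higher and 4 lower of 12 (3 and 4 adjusted over the list alone), with Cacna2d1 at -1.08. Adrenergic, angiotensin, endothelin and natriuretic signalling had 2 higher, Adra1d and Nr3c2, and 8 lower of 17 (2 and 9 adjusted over the list alone; camera adjusted p = 0.117). Clock genes had 4 higher, among them Per1, Per3 and Nfil3, and 3 lower, Arntl, Npas2 and Nr1d1, of 17 (4 and 3 adjusted over the list alone). Antioxidant genes had 7 higher and 6 lower of 21 (7 and 6 adjusted over the list alone), with Ephx2 at 7.69 ± 0.75 against 0.46 ± 0.19 FPKM. Unfolded protein response genes had 1 higher, Xbp1, and 3 lower, Ddit3, Sdf2l1 and Pdia6 (-0.44), of 15 (0 and 1 adjusted over the list alone). Schwann cell and glial markers had 2 higher, Cnp (0.43) and S100b, and 4 lower, Cdh19, Pmp22, Mal and Prx, of 9 (2 and 4 adjusted over the list alone). Smooth muscle markers had 1 higher, Kcnj8, and 3 lower, Rgs5, Pdgfrb (-0.67) and Notch3, of 11 (1 and 4 adjusted over the list alone). Adipocyte markers had 1 higher, Cidea (0.94), of 9 (1 adjusted over the list alone), and cell cycle genes 4 lower, Top2a, Cdk1, Ccnb1 (-0.49) and Ccna2, of 7 (5 adjusted over the list alone; camera adjusted p = 0.0772). The cell cycle list passed with median-of-ratios scaling (camera adjusted p = 0.0384) and without SHR replicate 4 (camera adjusted p = 0.0473), in the lower direction (adjusted p = 0.589 with an estimated correlation in all 8 libraries without that scaling).

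Over all genes of the adrenal gland, 5181 of 12589 were called, 2073 higher and 3108 lower, and 597 changed at least 2-fold. Higher calls made up 40.0%, or 53.1% with median-of-ratios scaling and 49.7% with quantile normalization. The carbonyl reductase gene Cbr1 was at 760 ± 106 FPKM in SHR and listed at 0 in all 4 WKY libraries, and Setd4 was at 21.8 ± 1.0 against 0.01 ± 0.02. LOC102556347, next to Setd4 in gene order, had the same pattern, at 398 FPKM in SHR and listed at 0 in WKY. Whether reads of these genes were placed elsewhere in WKY was not tested, so their levels are uncertain. Ddit4, an inhibitor of growth signalling, was at 337 ± 119 against 11.1 ± 4.02, Sptssb at 64.1 ± 28.7 against 1.48 ± 0.30 and Ndufa10l1, which is uncertain, at 30.4 ± 2.16 against 0.41 ± 0.12. In the other direction, Serpinc1, which encodes antithrombin, was at 0.02 ± 0.02 against 78.7 ± 6.86, Cd36 at 4.22 ± 1.39 against 262 ± 25.6, Cyp2a1 at 0.22 ± 0.09 against 40.0 ± 13.5, the fatty acid transporter gene Slc27a6 at 0.80 ± 0.13 against 48.1 ± 12.9 and the prolactin receptor gene Prlr at 9.40 ± 2.06 against 216 ± 15.6. Of 14 genes from earlier SHR genetics 3 were higher, Ephx2, Gstm1 and Add1, and 7 lower, among them Cd36, Endog (-1.46), Ogn (-1.09), Spon1 (-0.85) and Ndufc2 (-0.25) (3 and 8 adjusted over the list alone). Gstm1 (0.19, adjusted p = 0.0360) lost its call without any 1 library except WKY replicate 1 (adjusted p = 0.0659 to 0.0963), Add1 (0.21) without SHR replicate 1 (adjusted p = 0.0537), and Ndufc2 without SHR replicate 3 or 4 or WKY replicate 2 or 4 (adjusted p = 0.0516 to 0.0686) or with median-of-ratios scaling (adjusted p = 0.107).

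In the superior cervical ganglion, whose sympathetic neurons innervate the head and the heart, Th, Dbh, the noradrenaline transporter gene Slc6a2 and Npy, fixed genes for noradrenaline synthesis, uptake and cotransmission, had differences between -0.22 and 0.14. Th was at 764 ± 43.5 FPKM in SHR and 695 ± 17.9 in WKY (0.14, SE 0.04, adjusted p = 0.0767), Slc6a2 at 965 ± 132 and 1122 ± 101 (-0.22, adjusted p = 0.253), and Npy at 2303 ± 94.5 and 2144 ± 56.2 (0.10, adjusted p = 0.101). The neurotrophin receptor gene Ngfr (-0.04, adjusted p = 0.691) and the nicotinic receptor gene Chrna3 (0.16, adjusted p = 0.0951) did not pass. Dbh was lower in SHR, at 1746 ± 49.8 against 1968 ± 94.0 (-0.17, SE 0.04, adjusted p = 0.0186), and lost its call without SHR replicate 2 or WKY replicate 2 (adjusted p = 0.0561 and 0.0611). Th passed without SHR replicate 4 (adjusted p = 0.0168) and Chrna3 without WKY replicate 3 (adjusted p = 0.0143).

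The circadian clock list was the only one of 17 called in the ganglion. Of 15 members, 7 rose and Arntl, a transcription factor of the clock, fell (9 and 1 adjusted over the list alone). The camera adjusted p was 0.00389 (adjusted p = 0.950 with an estimated correlation). Clock members also moved both ways in the left ventricle (3 higher and 2 lower) and the adrenal gland (4 higher and 3 lower). The set test looks for 1 direction, so it can miss a change of this list there. In the ganglion Dbp, an output gene of the clock, was at 21.7 ± 6.58 against 7.35 ± 0.52 FPKM (1.4, SE 0.17, adjusted p = 0.00128), Ciart at 1.96 ± 0.57 against 0.40 ± 0.08 and Per3 at 5.30 ± 0.56 against 3.10 ± 0.27. The labels give neither time nor order of collection, so an effect of either on these genes cannot be told apart from strain. SHR replicate 1 stood apart, with Dbp at 31.5 against 17.6 to 19.1 in the other SHR libraries, and without it the list had a camera adjusted p of 0.00607. On the second principal component of the ganglion, 17.4% of the variance, SHR replicate 1 was at 10.7 with WKY replicates 1 and 4 at 11.4 and 12.8, and the other libraries were at -13.1 to -4.65. In this tissue 5 lists passed with the rank-based form of the set test, 2 with median-of-ratios scaling, and 2 to 4 without SHR replicate 1, 3 or 4 or WKY replicate 3 or 4.

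Genes of neuronal function in the ganglion changed singly. Chgb, a granule protein gene, rose to 151 ± 9.82 against 91.1 ± 4.10 FPKM, and Penk fell to 39.5 ± 9.81 against 298 ± 51.0. The granule and neuropeptide list had 4 higher, Chgb, Pam, Sst and Snap25, and 3 lower, Penk, Adcyap1 and Syt4, of 22 (7 and 3 adjusted over the list alone). The catecholamine list had 4 higher, among them Pts, Slc18a1 and Maob, and 3 lower, Dbh, Gch1 (-0.29) and Qdpr, of 14 (5 and 3 adjusted over the list alone). Neuronal identity had 2 lower, Gata2 (-0.24) and Eno2, of 20 (4 higher and 4 lower adjusted over the list alone). Ion channels had 1 higher and 3 lower, among the latter Scn1a and Chrnb4, of 25 (1 and 3 adjusted over the list alone). Neurotrophic factors had 2 lower, among them Gfra2 (-0.37), of 11 (1 higher and 2 lower adjusted over the list alone). Signalling receptors had 1 higher, Agtr1a, and 4 lower, the presynaptic receptor gene Adra2c (-0.70, SE 0.04, adjusted p = 3.19e-06), Agt, Ednrb and Edn1, of 18 (2 and 7 adjusted over the list alone).

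The remaining lists of the ganglion did not pass the set test. Matrix genes had 4 higher, Col8a1, Tgfb1, Tgfb3 and Comp, and 1 lower, Postn, of 31 (5 and 1 adjusted over the list alone). Oxidative phosphorylation had 2 lower, Ndufa10 and Ndufb8, of 31 (2 adjusted over the list alone; camera adjusted p = 0.0634). Immediate early genes had 2 higher, Ier3 (0.45) and Nr4a2, of 19 (2 adjusted over the list alone). Interferon response had 3 higher, Ifit1, Ifi44 and Ifih1, and 2 lower, Isg15 and Ifit2, of 23 (3 and 3 adjusted over the list alone). Ifit1 was at 4.06 ± 1.68 FPKM in SHR and listed at 0 in WKY. Without SHR replicate 3, whose mean of the list was 3.66 against 3.19 to 3.32 in the other SHR libraries, the interferon list passed in the lower direction (camera adjusted p = 0.00815; adjusted p = 0.980 with an estimated correlation in all 8 libraries). Unfolded protein response had 1 higher, Sdf2l1 (0.43), of 15 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0586). Leukocyte markers had 1 lower, Aif1, of 14 (1 adjusted over the list alone; camera adjusted p = 0.0586). Aif1 (-0.43) lost its call without SHR replicate 2, 3 or 4 or WKY replicate 3 (adjusted p = 0.0561 to 0.0724). Endothelial markers had none called of 12 (2 lower adjusted over the list alone; camera adjusted p = 0.0634). Adipocyte markers had 1 lower, Cidea, of 8 (1 adjusted over the list alone), a call lost without SHR replicate 2, 3 or 4 (adjusted p = 0.0613 to 0.0667). Glial markers had 1 higher, Cdh19, and 1 lower, S100b (-0.59), of 15 (3 and 1 adjusted over the list alone), and smooth muscle markers none of 10. Without a set test, none of 3 erythroid, 4 skeletal muscle, 3 adrenal cortex and 2 cell cycle genes passed (1 skeletal muscle gene higher adjusted over the list alone).

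The ganglion had 1402 of 12987 genes called, 827 higher and 575 lower, 109 of them by at least 2-fold. Higher calls made up 59.0%, or 53.5% with median-of-ratios scaling and 53.2% with quantile normalization. The largest higher genes were Ndufa10l1 (23.1 ± 1.24 against 0.16 ± 0.32 FPKM), Cbr3 (9.15 ± 1.14 against 0.06 ± 0.05), Setd4 (9.06 ± 0.14 against 0.14 ± 0.02), the peptide receptor gene Npy4r (16.8 ± 0.83 against 1.17 ± 0.31) and Tmem255b (49.1 ± 1.24 against 5.90 ± 1.56). The largest lower genes were the tubulin gene Tuba1c (5.10 ± 3.56 against 175 ± 12.7), Perp (0.94 ± 0.33 against 20.7 ± 1.36), Penk, Hist1h2bk and Tyrp1, an enzyme gene of melanin synthesis (2.20 ± 0.94 against 16.1 ± 1.91). Tuba1c, Hist1h2bk and Ndufa10l1 are uncertain because of near-identical copies. Of 14 genes from earlier SHR genetics, 5 were higher, among them Ephx2 (2.50), Gstm1, Stim1 and Spon1 (1.20), and 2 lower, Cd36 and Endog (-0.92), with the same counts adjusted over the list alone. Cd36 (-1.55, adjusted p = 0.0209) lost its call without SHR replicate 2, 3 or 4 or WKY replicate 1 (adjusted p = 0.0583 to 0.0618), and Stim1 (0.18, adjusted p = 0.0452) without any 1 library except WKY replicate 4 (adjusted p = 0.0518 to 0.121).

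**Figure D2:**
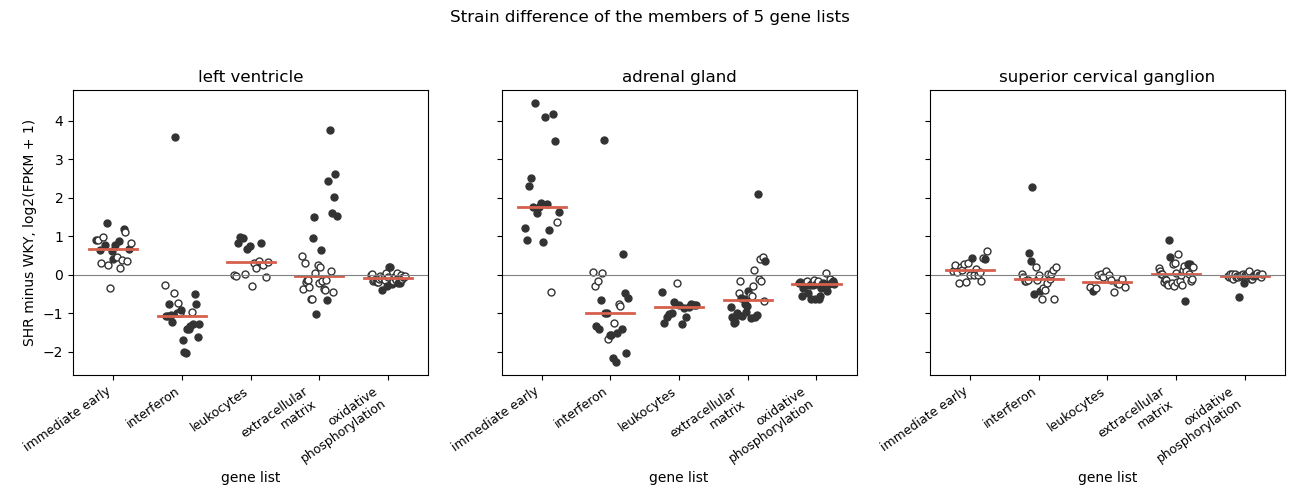
Difference of SHR minus WKY on the log2(FPKM + 1) scale for each measured member of 5 gene lists in the 3 tissues; filled points passed an adjusted p of 0.05, open points did not, and the red line is the list's median. Immediate early genes have medians of 0.66, 1.76 and 0.12 in the left ventricle, adrenal gland and ganglion, and leukocyte markers 0.32, -0.84 and -0.18.

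The strain difference of many genes depended on the tissue. Spp1 rose in the left ventricle and the adrenal gland and was at 7.35 against 7.0 FPKM in the ganglion, and its difference between ganglion and ventricle was -3.69 (SE 0.59, adjusted p = 2.71e-04). Penk was higher in the SHR ventricle (202 against 83.0) and lower in the ganglion, a difference of -4.12 (SE 0.30, adjusted p = 5.19e-09). Serpinc1 and Cyp2a1 were below 1 FPKM in SHR and WKY of both other tissues, so that the loss in the adrenal gland gave differences of -6.30 and -4.96 against the ventricle and -6.25 and -5.01 against the ganglion. Slc27a6 differed by -4.68 between adrenal gland and ventricle. Tuba1c, lower in the ganglion and at 100.02 against 80.8 FPKM in the adrenal gland (adjusted p = 0.0344), differed by -3.96 between ganglion and ventricle (adjusted p = 0.0108) and by 5.37 between adrenal gland and ganglion (adjusted p = 4.14e-04). Cbr1, listed at 0 in WKY of all 3 tissues, was at 2.20 FPKM in the SHR ventricle and 6.09 in the SHR ganglion, against 760 in the SHR adrenal gland. The chemokine gene Ccl21 was at 6.97 against 64.5 in the ventricle and 17.7 against 10.2 in the ganglion (4.97, SE 1.45, adjusted p = 0.0265). The Ccl21 call was lost with array weights (adjusted p = 0.0632) and without LV SHR replicate 1 or 3, LV WKY replicate 1 or 4, SCG SHR replicate 4 or SCG WKY replicate 3 or 4 (adjusted p = 0.0505 to 0.0617; LV, left ventricle; SCG, superior cervical ganglion), and that of Tuba1c between ganglion and ventricle with a pseudocount of 0.1 (adjusted p = 0.321). Of 14682 genes in the joint model, 5072 had a different strain difference in the adrenal gland and the left ventricle, 2119 in the ganglion and the left ventricle, and 4379 in the adrenal gland and the ganglion. These include genes expressed in only some of the tissues, whose difference is near 0 where they are silent. For such genes the contrast can restate where the gene is expressed. Genes tested in all 3 tissues numbered 10902, and the counts among them were not computed.

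A set of genes differed the same way in every tissue. Ndufa10l1, Setd4, the class I gene RT1-CE2 and Ephx2 were higher in SHR in all 3 tissues, Setd4 by 2.61, 4.50 and 3.14 and Ephx2 by 1.83, 2.58 and 2.50 in ventricle, adrenal gland and ganglion. Cd36, the histocompatibility genes RT1-CE10 and RT1-Bb, and Retsat, a retinol saturase gene, were lower, Retsat at 50.7, 296 and 18.3 FPKM in SHR against 181, 693 and 63.8 in WKY. Levels of RT1 genes are uncertain, since they have near-identical copies. Among 10902 genes tested in all 3 tissues, 79 were higher everywhere, where independent lists would give 8.48, and 101 lower, where they would give 10.8. The total of 180 fell to 63 to 73 with a replicate number left out of all groups, each of the 4 numbers included, and to 115 with the stricter filter. Of 248 genes called in all 3 tissues, 180 kept 1 direction.

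In the authors' deposited table, 3000 genes had a q-value under 0.05 in the left ventricle, 6036 in the adrenal gland and 1692 in the ganglion. In the authors' deposited table and the limma test together, 2311, 4466 and 1211 genes were called, all with the same sign.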

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

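The tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries.

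The number of genes called exceeded that of every other split of the 8 libraries into 4 and 4 in each tissue. Only 1 of 35 splits, the real one, gave 2644 genes in the left ventricle (highest other 2), 5181 in the adrenal gland (highest other 1) and 1402 in the ganglion (highest other 3). This argues against an arbitrary grouping of these libraries, at the smallest share that 35 splits allow. The other splits mix the strains, so their low counts do not measure chance differences between a few rats. Those stay open, since the labels do not say that the libraries came from separate rats. Draws of strain labels within each tissue decide nothing for the differences between tissues, since they remove the strain differences themselves and do not test whether these are equal: 1 of 100 draws gave 5072, 2119 and 4379 genes, and the highest other draws, 3643, 836 and 3846, were draws in which the labels of 1 tissue coincided with the strains. They decide nothing for genes changed in all 3 tissues either (1 of 100 draws gave 180, highest other 0), since other splits of a tissue called at most 3 genes and could not overlap in more. Chance is not excluded for the number of gene lists called: 6 of 35 splits called at least the 7 lists of the left ventricle (highest other 8), 9 of 35 at least the 9 of the adrenal gland (highest other 12), and 35 of 35 at least the 1 of the ganglion (highest other 10).

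Immediate early genes were higher in the SHR adrenal gland, 16 of 18 members. A single library is argued against, since 16 or more members were called higher with any 1 of the 8 libraries left out. A shifted circadian clock stays open. With a clock score of each library in the model the median strain difference was 1.77 against 1.76 without it, but strain accounted for 6.54% of the variance of that score, so the model could not take up a shift between strains. Handling or the order of collection cannot be told apart from strain, because the labels give neither time nor order; 14 of 18 members differed between adrenal gland and ganglion, which does not decide it, since tissues need not respond alike. A strain difference in adrenal stimulation remains an open biological explanation and was not tested.

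Chromaffin genes were lower in the SHR adrenal gland, 10 of 12 markers with a median of -0.92. A smaller share of medulla in the tissue would lower strongly expressed markers confined to it by about the same amount. The differences spanned 2.22 on the log2 scale, from Penk (-2.43) to Npy (-0.21). Their spread was larger than in any other split of the libraries (exact permutation p = 0.0286, 1-sided, the smallest that 35 splits allow). So the 12 markers did not all fall by 1 amount. This does not decide about a smaller medulla, since 1 marker with its own strain difference is enough to widen the spread. Penk and Npy, at the ends of the range, were at 16.1 and 19.5 FPKM in WKY, against 850 for Chga. Penk, also lower in the ganglion, sets the range. Without it the range began at -1.36 (Dbh), and that spread was not tested. With 5181 of 12589 genes called in this tissue, differences of single genes can widen the spread, so it does not measure the share of medulla. More cortex at the cost of every other cell type would also lower the chromaffin markers alike. The same spread of 2.22 leaves it undecided, for the same reasons. The scores of leukocyte (-0.86), endothelial (-0.56) and chromaffin markers (-0.98) spanned 0.422 (exact permutation p = 0.171, 1-sided) and do not argue against it. Scores of glial (-0.22) and smooth muscle markers (-0.23), whose members went both ways, fell less and were not part of that test. Scaling is argued against, as the median was -0.85 with median-of-ratios scaling. A smaller medulla or a larger cortex, together with changes of single genes, may still contribute, and a strain difference in chromaffin cells stays open.

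Ndufa10l1 was higher and Ndufa10 lower in SHR in every tissue. Reads shared between the copies are consistent with the values: the summed FPKM of both was 296 ± 1.49 against 281 ± 23.3 in the left ventricle, 105 ± 3.57 against 115 ± 3.86 in the adrenal gland and 78.8 ± 5.33 against 84.1 ± 1.64 in the ganglion. The largest strain difference of the sum was -0.13 on the log2 scale, beside differences of 4.41 to 5.59 for Ndufa10l1. The contrast of these log2 values decides nothing, since Ndufa10 made up most of the sum (211 FPKM against 84.5 for Ndufa10l1 in the SHR left ventricle). In FPKM, a rise of Ndufa10l1 alone would have raised the sum by about its SHR level. That level was 84.5, 30.4 and 23.1 in ventricle, adrenal gland and ganglion. The sum was 296 against 281 in the ventricle and lower in SHR in the other tissues. This argues against a rise of Ndufa10l1 with Ndufa10 unchanged. The part that shared reads would give is the lower Ndufa10, by -0.40, -0.62 and -0.59 in ventricle, adrenal gland and ganglion. A strain variant that directs reads to either copy and a true difference in expression were not separated.

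Strain differences that themselves differed between tissues, by the interaction test, were found for 5072, 2119 and 4379 genes, which include genes expressed in only some of the tissues. Against the left ventricle, the adrenal gland differed by 8.11 for Cbr1, -6.30 for Serpinc1, -4.96 for Cyp2a1 and -4.68 for Slc27a6, and the ganglion by 4.97 for Ccl21, -4.12 for Penk, -3.96 for Tuba1c and -3.69 for Spp1. Ccl21 did not pass without LV SHR replicate 1 or 3, LV WKY replicate 1 or 4, SCG SHR replicate 4 or SCG WKY replicate 3 or 4 (adjusted p = 0.0505 to 0.0617). Between adrenal gland and ganglion the differences were 7.25 for Cbr1, -6.25 for Serpinc1, 5.37 for Tuba1c and -5.01 for Cyp2a1. For Cbr1, listed at 0 in WKY, these values depend on the pseudocount, and reads placed elsewhere in WKY were not tested.

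A library lay far from the other 3 of its group in 21 of 324 groups and measures examined, where chance gives about 5%. In the left ventricle these were FPKM of Ccdc78 (0.18 in SHR replicate 3), Oas1g (3.03, SHR 2; the others are listed at 0), Tgfb2 (24.5, SHR 2), Stat2 (21.5, SHR 2), Ndufb8 (976, WKY 3), Btg2 (27.2, WKY 1), Egfl7 (79.6, WKY 4) and Tbx5 (5.89, WKY 1). In the adrenal gland they were Sptssb (107 in SHR replicate 3, others 47.6 to 51.2), Setd4 (0.04, WKY 3), Slc27a6 (67.4, WKY 2), Ndufb8 (175, WKY 1), Gap43 (4.77, WKY 2), Ifit1 (0 in WKY 2) and Ephx2 (0.75, WKY 3). In the ganglion they were Dbp (31.5 in SHR replicate 1, others 17.6 to 19.1), Ndufa10l1 (0.64, WKY 1), Setd4 (0.16, WKY 1), Tmem255b (3.61, WKY 3), Spon1 (1.4, WKY 2) and the share of FPKM in the 10 highest genes (5.22% in WKY 3). Being relative to the range, the rule also picks small differences near 0, such as Setd4 in the ganglion (0.16 against 0.13 in the other WKY libraries).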

How the results depend on the processing

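The 9 lists called in the adrenal gland stayed called without any 1 library (9 to 10 lists), and the left ventricle had 5 to 8. Of 185 recomputed counts, 166 stayed within 1.5 times the main value and 19 did not. Requiring a 2-fold change left 252 genes in the left ventricle, 597 in the adrenal gland and 109 in the ganglion, by construction. With an estimated correlation camera called 0 lists in each tissue (unadjusted p under 0.05 in 2, 0 and 0 lists; the rank-based form called 7, 9 and 5). In the ganglion the number of lists, 1 in the main test, was 5 with the rank-based form, 2 with median-of-ratios scaling, and 1 to 4 without a library in turn; the cause was not tested. Genes changed in all 3 tissues numbered 115 with the stricter filter, which tests fewer genes, and 63 to 73 without a replicate number, which leaves fewer samples. With single libraries left out, the counts were 1858 to 2672, 4118 to 5154 and 950 to 1210 genes in the 3 tissues and 4617 to 5040, 1665 to 2313 and 3864 to 4469 for the differences between tissues. Scaling moved the share of higher calls, in the left ventricle from 43.3% to 52.1% with median-of-ratios scaling and 49.3% with quantile normalization, and in the adrenal gland from 40.0% to 53.1% and 49.7%. In the ganglion the share moved from 59.0% to 53.5% and 53.2%. Median-of-ratios scaling kept 4563 of the 5181 genes of the adrenal gland; the median of all genes there moved from -0.04 to 0.02. No named gene changed direction under a pseudocount of 0.1, that scaling, the replicate block or the loss of a library; with a library left out, 58 of 1396 recomputed differences lost their call and 4 gained one. Whether the replicate numbers pair the libraries is undecided: deviations of same-numbered libraries correlated at -0.15 to 0.23 between strains in a tissue (5 of 12 above 0.1) and at -0.14 to 0.18 between tissues (3 of 24), and 3, 3 and 1 of the 4 numbers in the left ventricle, adrenal gland and ganglion correlated best with their own. SHR replicate 2 stood apart in the interferon list, and SHR replicate 3 on the second principal component, in both the left ventricle and the adrenal gland. With the replicate number as a block the counts were 2407, 5182 and 1206 genes, 165 in all 3 tissues, and 7, 9 and 4 lists; with strain and number as a random block the differences between tissues were 5090, 2129 and 4388. Of 162 named differences the block changed 4 calls: Oas1g in the left ventricle (adjusted p = 0.0692) and Gstm1 in the adrenal gland (adjusted p = 0.0516) did not pass, and Myh6 and Myh7 in the left ventricle did (adjusted p = 0.0149 and 0.0324). FPKM without read counts sets no limit of detection for genes listed at 0.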

Other observations

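The comparison of lists between tissues and the means of lists in single libraries were chosen after the data were examined.

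The interferon response varied within SHR. In SHR replicate 2, Usp18 was at 21.9 FPKM in the left ventricle and 11.4 in the adrenal gland, with 7.61 to 9.06 and 1.3 to 1.42 in the other SHR libraries, and Mx2 was at 70.1 and 109, with 14.6 to 22.0 and 19.9 to 28.3. Without SHR replicate 2 the interferon list had a camera adjusted p of 2.74e-21 in the left ventricle and 6.89e-10 in the adrenal gland (in all 8 libraries, adjusted p = 0.673 and 0.722 with an estimated correlation). That library was singled out after its mean was seen, so the smaller p-values follow from the choice. They use the preset correlation of 0.01, where the estimates in all 8 libraries were 0.87 and 0.82. The form with an estimated correlation was not run without it. In the ganglion, SHR replicate 3 had the highest mean of the list among the SHR libraries. Adipocyte markers also varied between libraries of a strain, with means of log2(FPKM + 1) from 2.04 to 4.15 in SHR and 2.48 to 4.88 in WKY in the adrenal gland, and from 1.49 to 2.69 and 0.74 to 3.51 in the ganglion. WKY replicates 1 and 4 of the ganglion had the highest means of smooth muscle markers in that tissue, at 2.74 and 2.80, and of endothelial markers, at 3.25 and 3.35.

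Camera on the interaction contrasts of 11 lists shared by the 3 tissues compared the shifts themselves. Leukocyte markers differed between adrenal gland and ventricle by a median of -1.14 with 15 of 16 members past the threshold (camera adjusted p = 2.55e-07; adjusted p = 0.561 with an estimated correlation). Matrix genes were lower in the adrenal gland relative to the ventricle by a median of -0.95 (17 of 32 members; camera adjusted p = 1.39e-04; adjusted p = 0.561 with an estimated correlation). Immediate early genes differed between adrenal gland and ganglion by 1.36 (15 of 22; camera adjusted p = 2.83e-11; adjusted p = 0.332 with an estimated correlation). Interferon-response genes differed between ganglion and ventricle by 0.96 (8 of 24; camera adjusted p = 4.96e-06; adjusted p = 0.598 with an estimated correlation). Clock genes did not pass for any pair of tissues (camera adjusted p = 0.613 to 0.969). A test for 1 direction can miss a change of this list, whose members moved both ways.

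A hypothesis is that genes changed in all 3 tissues mark strain differences at single places in the genome. Of the 180 genes, 175 could be placed in the gene order of assembly GRCr8 among 10556 tested genes, and 13 pairs were direct neighbours, against a mean of 2.88 and a highest value of 11 in 10000 random draws (permutation p = 1e-04, 1-sided, the smallest these draws can give). Draws from genes called in 1 tissue alone gave a mean of 2.87 (permutation p = 1e-04). Of the 13 pairs, 8 shared their direction, for example Setd4 with LOC102556347, and 5 did not, for example Ifi44l with Gipc2. Pairs of RT1 genes, whose reads can be split between copies, made up much of the excess: without RT1 genes 6 pairs remained, against a mean of 2.43 (permutation p = 0.0350). The excess is consistent with local strain differences, and reads misplaced between neighbouring copies may contribute to it.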
